A study of Homo sapiens with 2 samples.

How the data were processed

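Single-cell RNA sequencing was read from 2 libraries of naive H9 cells, an established human embryonic stem cell line. Per the labels' protocols, the cells grew in RSeT medium with 10 nM DZNep and 5 nM TSA and received 25 nM of an oligonucleotide carrying a green dye. The oligonucleotide was either antisense to LINE1 RNA (ASO-L1) or its sense control (SO-L1). Trans-ISRIB at 0.7 µM, emricasan at 5 µM and Y-27632 at 10 µM were taken away after 24 hours. After 48 hours 100000 dye-positive cells were sorted, and 12000 cells per library were aimed for with the 10x 3' v3 chemistry at over 65000 reads per cell. The sort keeps cells that took up the oligonucleotide, in both groups.

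The deposited files hold raw UMI counts per gene and barcode, made with Cell Ranger 7.1.0 on hg38, per the file headers and the submitters' processing notes. Gene symbols and identifiers come from the authors' gene tables, with 36601 genes in each. The annotation release, the cell-calling settings and whether intronic reads were counted are not given in the sources used here. The deposited tables hold genes and no transposon families, so the level of LINE1 RNA itself was not measured here. Gene positions, types and lengths come from GENCODE 29 on GRCh38, matched by gene identifier. Of 658 entries in the gene lists, 7 were matched by identifier under another symbol and 2 had no match.

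Each group has 1 library, so cells are not replicates and no p-value is given anywhere. Intervals of ratios and shares cover counting error only. Those of list medians cover the spread between member genes, taken as independent. No interval covers the spread between libraries. The intervals of ratios treat each UMI as independent and leave out the spread between cells. Cells were kept with at least 1000 detected genes and under 20% of UMIs from mitochondrial genes. The SO-L1 library kept 6553 of 13070 barcodes and 273349662 UMIs. The ASO-L1 library kept 9084 of 11659 barcodes and 499106701 UMIs. Scrublet, as run in scanpy 1.11.5, called 0 doublets in either library, so it did not work as a caller and no cell was left out on its calls.

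UMIs were summed over the kept cells of a library and divided by the total to give CPM. Each gene's ratio of ASO-L1 over SO-L1 carries an exact conditional binomial (Clopper-Pearson) 95% interval. Where a sum was 0 UMIs, a floor of 3 was used in its place for the fold. A gene counted as measured in a list from 50 UMIs over both libraries. Each list is described by the median log2 ratio of its measured members, the 95% order-statistic interval of that median, and the members at least 1.5-fold higher or lower. Its percentile among 10000 random lists of the same size is also given, each member being replaced by 1 of the 200 genes nearest in expression. Genes at least 2-fold apart were counted among genes with at least 100 UMIs whose interval excludes 1.

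The gene lists, the named-gene rule, the tests and the first set of alternatives were fixed before the data were examined. The rule names, per comparison, the 10 genes highest and the 10 lowest by the bound of the interval nearest to 1 among genes with at least 500 UMIs. Clone-style names, LINC names and mitochondrial genes are left out of that part. It also names, from each list described, the 2 members with the largest ratio and the 2 with most UMIs, and always ZSCAN4, TPRX1, LEUTX, DUXA, DUX4, KLF17, POU5F1, SOX2, NANOG, EZH2, EED, SUZ12, NCL, FBL, NPM1, TRIM28, CDKN1A and GATA3. Genes named outside the rule are said to be so, and 1 gene that the rule names is not reported here. Of 40 listed genes of the 8-cell (8C) stage, 38 are in the tables. Members of the PRAMEF, TRIM43, TRIM48, TRIM49, MBD3L, RFPL and DUX families share sequence with close copies, and their single values are uncertain.

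To compare shares of cells, each cell was thinned without replacement to 8000 UMIs, the 10th percentile of the SO-L1 library rounded down to a multiple of 500. This left out 649 SO-L1 and 520 ASO-L1 cells that were shallower. A cell was counted by how many of 20 8C calling genes had a UMI, with exact Clopper-Pearson intervals for shares. The share expected if the calling genes' UMIs were spread evenly over cells was computed beside it. Cells with 3 or more calling genes were compared with the other cells of their own library on all UMIs. The thinned cells of both libraries were clustered with scanpy 1.11.5 and leidenalg 0.10.2 on 2000 variable genes, 30 principal components and 15 neighbours at resolution 0.5. A cluster was named only from the fixed markers.

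Splitting the cells at 2% mitochondrial UMIs was chosen after that share was seen to fall into separate ranges. In comparisons between or within these classes, mitochondrial genes were left out of the total, except among the alternatives, where they stay in. Barcode sequences present in both libraries were compared after they were noticed. The alternatives tried were no cell filter, a stricter one (2000 genes, 10% mitochondrial UMIs), other scalings, other UMI minimums, thinned sums, other numbers of calling genes, other thinning depths and other cluster settings. Alternatives added after seeing the data were leaving out barcodes deeper in the other library, leaving out the highest Scrublet scores, each mitochondrial class alone, 4 or more calling genes, and clusters without the 8C genes. The share of the cells with 3 or more calling genes that fall in 1 cluster was also added then, after the planned cluster shares had been seen to change with the setting.

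The steps were tested on simulated data drawn from the real gene means for the pooled comparison of 22865 genes. The intervals covered the simulated ratio in 93.2% to 98.0% of genes, and every gene simulated 2-fold or 4-fold apart was found at 1.5-fold in the right direction. Counts were drawn independently, without cells, so this coverage does not speak to genes whose UMIs are concentrated in few cells. Of unchanged simulated lists of 20 genes, 8% lay outside the central 95% of random lists. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.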

Results

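Transcripts were counted in single naive H9 human embryonic stem cells, 1 library from cells given the sense control (SO-L1) and 1 from cells given the oligonucleotide antisense to LINE1 RNA (ASO-L1). Kept cells held a median of 42314 UMIs and 7830 genes in SO-L1, and 53959.5 UMIs and 8273 genes in ASO-L1. Mitochondrial genes took a median of 7.86% of UMIs in SO-L1 and 6.40% in ASO-L1. The filter kept 50.1% (95% interval 49.3% to 51.0%) of SO-L1 barcodes and 77.9% (77.1% to 78.7%) of ASO-L1 barcodes. Most of the others, 6045 in SO-L1 and 2045 in ASO-L1, had under 1000 genes. With 1 library per group, no difference below has a replicate check, and "higher" and "lower" compare these libraries. Intervals cover counting error only, except those of list medians, which cover the spread between member genes.

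The series title concerns control of the 8C state, the programme of the human embryo at genome activation, by LINE1 and PRC2. Genes of that programme were mostly higher in the ASO-L1 library. Of the 21 listed 8C genes measured, 17 were at least 1.5-fold higher, 3 lower and 1 in between. ZSCAN4, a zinc finger gene that marks the 8C stage (ENSG00000180532, chromosome 19, 57668935 to 57679152), was 7.66-fold higher (6.24 to 9.50; 98 UMIs in SO-L1 and 1371 in ASO-L1). In SO-L1, 72 of its UMIs came from 10 cells, a clustering that the interval leaves out. TPRX1, a homeobox gene of the 8C stage (ENSG00000178928, chromosome 19, 47801243 to 47819051), was 6.87-fold higher (6.22 to 7.60). KHDC1L (ENSG00000256980, chromosome 6, 73223544 to 73225770) was 8.59-fold higher (8.27 to 8.93), from 10.2 to 87.6 CPM.

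Among the other 8C genes, ZNF280A was 9.53-fold and SLC34A2, a phosphate transporter, 9.35-fold higher in ASO-L1. RFPL2 was 8.64-fold higher, though its family shares sequence. KLF17, a transcription factor of early embryos and naive cells, was 3.50-fold higher and DUXA 4.08-fold (2.55 to 6.87; 20 and 149 UMIs). The 2 members with most UMIs, CCNA1, a cyclin, and PNP, a purine salvage enzyme, were 4.05-fold and 1.96-fold higher. The members lower in ASO-L1 were ARGFX at 0.528 times the SO-L1 level, DPRX at 0.522 times and RFPL4B at 0.122 times, the last on 45 and 10 UMIs. These 3 and H3.Y, the member in between at 1.33-fold, were named after their values were seen. LEUTX had 2 and 20 UMIs, a ratio of 5.48 (1.33 to 48.3), and DUX4 had 0 and 1, so no fold is given. The list's median log2 ratio was 2.03 (0.97 to 2.94), at percentile 100 of random lists.

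**Figure D1:**
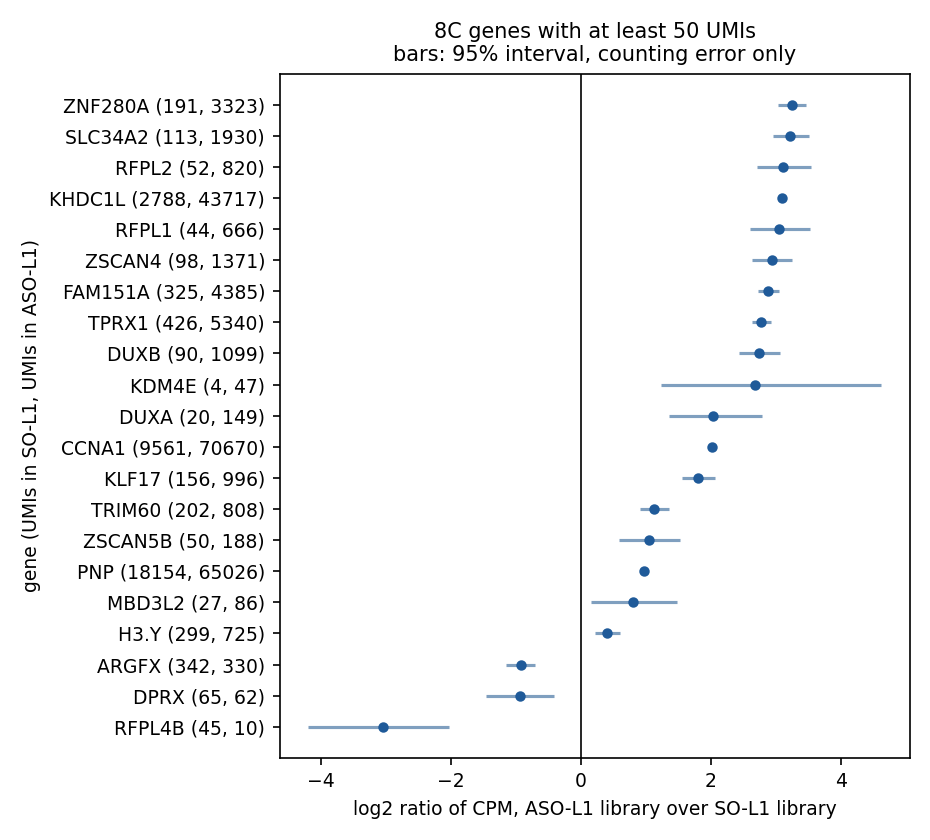
The log2 ratio of CPM in the ASO-L1 library over the SO-L1 library for each 8C gene with at least 50 UMIs, with its UMIs in each library and 95% intervals for counting error. Of the 21 genes, 17 lie at least 1.5-fold above equal levels.

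Pluripotency genes showed smaller and mixed differences. General pluripotency genes had a median of −0.09 (−0.36 to −0.02), with 0 of 17 at least 1.5-fold higher and 2 lower, GDF3 at 0.613 times and TERF1 at 0.641 times. The core factors stood at 0.915 times for POU5F1, 0.713 for SOX2 and 0.985 for NANOG, and LEFTY2 at 0.936. Naive genes had 11 of 27 higher and 6 lower (median 0.18), among them the placental phosphatases ALPP at 10.8-fold and ALPG at 3.97-fold, with DPPA4 at 1.11-fold and UTF1 at 0.675 times. Primed genes had 5 of 22 higher and 4 lower (median 0.18), with ZIC2 at 4.80-fold and DUSP6, a brake on ERK signalling, at 3.87-fold on 52 and 367 UMIs. The most abundant primed genes, CD24 and FGF2, stood at 0.864 and 0.990 times. In cells below 2% mitochondrial UMIs alone, the general median was −0.60 and the primed median −0.54, the latter with the opposite sign.

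Genes of other lineages were higher in ASO-L1 in several lists. Mesoderm genes had 8 of 11 higher and 0 lower (median 0.86, 0.04 to 2.55), with the organiser gene GSC at 12.2-fold, LHX1 at 5.87-fold, TWIST1 at 3.05-fold and MIXL1 at 1.82-fold. Trophectoderm genes had 9 of 19 higher and 1 lower (median 0.53, 0.20 to 0.85), with the tight junction gene CLDN4 at 3.29-fold, GATA3 at 1.80-fold and the keratin KRT18 at 1.29-fold. Amnion genes had 6 of 12 higher and 1 lower (median 0.58, 0.10 to 0.99), with ANXA3 at 4.09-fold and HEY1, a Notch target, at 4.08-fold. Fibroblast genes had 4 of 7 higher and 0 lower (median 0.72, −0.24 to 2.59), with TAGLN at 6.01-fold and the intermediate filament gene VIM at 3.51-fold. Primitive endoderm genes had 6 of 17 higher and 4 lower (median 0.06), with GATA6 at 8.42-fold and PDGFRA at 0.583 times. Neuroectoderm genes had 2 of 10 higher and 2 lower (median −0.19), with TUBB3, a neuronal tubulin gene, at 0.871 times.

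PRC2 deposits the repressive H3K27me3 mark, and regulators known as its targets were mostly higher. Of 30 measured, 19 were at least 1.5-fold higher and 3 lower (median 0.99, 0.39 to 1.67, percentile 100). This list shares members with the lineage lists above, PAX3 among them, so it is not a separate observation from those. SIX2 was 25.9-fold higher (9.94 to 96.0) on 4 and 189 UMIs, DLX2 9.20-fold on 19 and 319, CCND2 1.31-fold, and IRX2 0.654 times the SO-L1 level. The PRC2 factors themselves had 2 of 14 higher and 2 lower (median 0.09), with the catalytic subunit gene EZH2 at 0.662 times, EED at 1.42-fold, SUZ12 at 1.06-fold, PHF1 at 1.89-fold and JARID2 at 0.926 times. DZNep, present in both cultures, acts on the methylation that PRC2 carries out.

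Nucleolar and rRNA synthesis genes had 10 of 55 higher and 0 lower (median 0.19, 0.07 to 0.43). The polymerase I genes ZNRD1 and RRN3 were 2.16-fold and 2.05-fold higher, and the nucleolar protein genes NPM1, NCL and FBL 1.25-fold, 1.12-fold and 1.17-fold. Genes that silence LINE1 and other repeats had 0 of 28 higher and 1 lower (median −0.08, −0.24 to 0.14). That 1 was SAMHD1, a nucleotide hydrolase that restricts retroelements, at 0.471 times, while the DNA methyltransferase gene DNMT3B stood at 0.714 times and the corepressor gene TRIM28 at 1.03-fold. Splicing factor genes had 2 of 26 higher and 0 lower (median 0.21), TRA2B at 1.65-fold and HNRNPA2B1 at 1.55-fold. ZNF genes had 63 of 495 higher and 35 lower (median 0.10), and ribosomal protein genes 4 of 80 higher and 2 lower (median 0.14), RPL23A at 2.29-fold and RPL12 at 0.551 times.

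Of the stress lists, only that of the integrated stress response had a median interval that leaves out equal levels. Over all genes with at least 100 UMIs, 16.6% were at least 1.5-fold higher and 17.1% lower, a background for the counts. Integrated stress response genes had 11 of 23 higher and 0 lower (median 0.53, 0.29 to 1.41, percentile 100), with the transcription factor genes ATF5 at 5.36-fold and CEBPB at 4.99-fold, the amino acid transporter gene SLC3A2 at 2.66-fold and the chaperone gene HSPA5 at 0.911 times. Targets of p53 had 6 of 27 higher and 4 lower (median 0.31, −0.06 to 0.58), with GADD45A at 4.68-fold, PLK2 at 4.10-fold and the cell cycle inhibitor gene CDKN1A at 2.00-fold. That median was −0.13 in cells below 2% mitochondrial UMIs alone and 0.59 in the others (0.57 with mitochondrial genes left out of the total). Apoptosis genes had 5 of 21 higher and 1 lower (median 0.33, −0.06 to 0.58), with BIK at 2.39-fold and CYCS, cytochrome c, at 1.29-fold. Interferon response genes went the other way, with 11 of 27 lower and 5 higher (median −0.49, −1.01 to 0.30), among them IFIT3 at 0.237 times, IFIT2 at 0.262 times and BST2 at 0.497 times. That median was −0.76 (14 of 26 lower, 6 higher) in cells below 2% mitochondrial UMIs and −0.11 (4 of 25 lower, 5 higher) in the others.

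Cholesterol synthesis genes were lower in ASO-L1, 8 of 22 by at least 1.5-fold and 0 higher (median −0.51, −0.81 to −0.21, percentile 0). DHCR7, which makes the last step to cholesterol, stood at 0.352 times and SREBF2, a transcription factor of the pathway, at 0.567 times. Glycolysis genes had 1 of 21 higher and 4 lower (median −0.13), with the glucose transporter gene SLC2A3 at 2.27-fold and GAPDH at 0.778 times. Mitochondrially encoded genes had a median of −0.35 (−0.50 to 0.00), with 0 of 13 higher and 1 lower, MT-ATP6 at 0.629 times. G2M genes had 12 of 54 higher and 1 lower (median 0.22), with UBE2C at 2.53-fold, CENPA at 2.29-fold and TUBB4B at 0.757 times. S phase genes had 4 of 43 higher and 1 lower (median 0.10), with GINS2 at 0.443 times. Oocyte genes had 5 of 15 higher and 3 lower (median −0.06), with OOEP at 1.81-fold and KHDC3L at 0.659 times. In cells below 2% mitochondrial UMIs and in the others, the medians were −0.29 and −0.58 for cholesterol, 0.17 and −0.23 for glycolysis, and 0.09 and −0.36 for mitochondrially encoded genes. They were 0.59 and 0.05 for G2M and 0.39 and 0.03 for S phase genes.

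**Figure D2:**
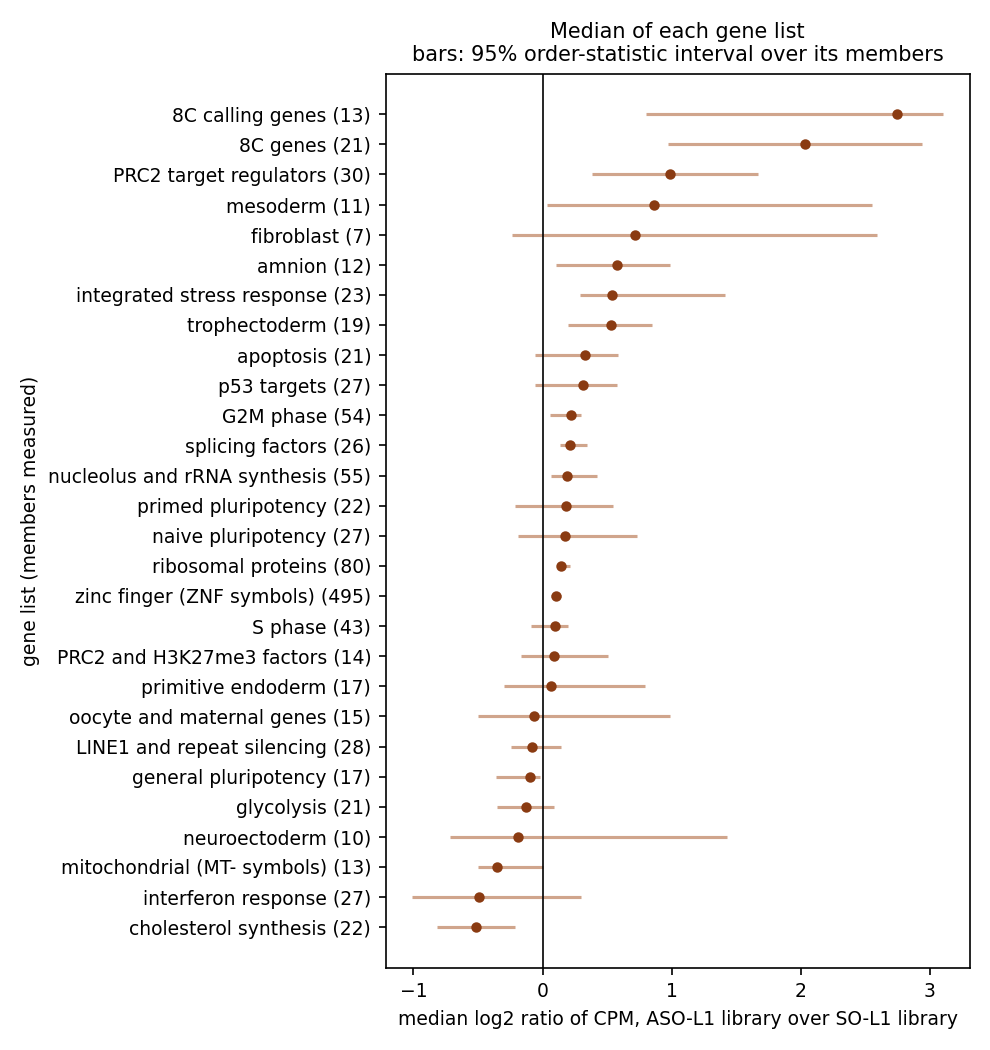
The median log2 ratio of CPM in the ASO-L1 library over the SO-L1 library for each gene list, with the members measured and 95% order-statistic intervals. The 8C lists lie highest, and cholesterol synthesis lies lowest at −0.51.

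Over all genes with at least 100 UMIs, 1752 of 22863 (7.66%) were at least 2-fold higher in ASO-L1 and 1350 (5.90%) at least 2-fold lower. At 1.5-fold, the size used in the list counts, 3792 (16.6%) were higher and 3919 (17.1%) lower. The genes highest by the rule were KRT75, a keratin, at 53.5-fold (34.1 to 89.0), CCL4, a chemokine, at 44.6-fold (22.5 to 104), MYL2 at 25.9-fold, ECM1 at 21.4-fold, AQP1, a water channel, at 20.6-fold, IL24 at 18.9-fold, CDH16 at 17.6-fold, ANKRD1 at 16.6-fold, TRH at 14.6-fold and CER1, a secreted Nodal and BMP antagonist, at 14.4-fold. The lowest were STPG2-AS1 at 0.186 times, TMEM179 at 0.204, the Notch target HES5 at 0.210, DENND6A-AS1 at 0.231, BHMT2 at 0.235, IFIT3 at 0.237, XDH, a purine-degrading oxidase, at 0.241, SYNPR-AS1 at 0.249, CGREF1 at 0.253 and the calcium channel gene RYR2 at 0.270. Antisense genes are uncertain, because strand use in the counting is not given in the sources used here. In thinned cells 1071 genes were at least 2-fold higher and 834 at least 2-fold lower.

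Cells with several 8C genes at once were rare in both libraries and more frequent in ASO-L1. At 8000 UMIs per cell, 3 or more calling genes were found in 10 of 5904 SO-L1 cells (0.169%, 0.081% to 0.311%) and 153 of 8564 ASO-L1 cells (1.79%, 1.52% to 2.09%), a ratio of 10.5. Without thinning the shares were 0.336% and 4.90%. A UMI of KHDC1L was found in 1.74% of SO-L1 and 12.1% of ASO-L1 cells, of ZNF280A in 0.644% and 3.50%, of TPRX1 in 0.711% and 3.44%, and of ZSCAN4 in 0.186% and 0.993%. At least 1 calling gene was found in 3.51% and 15.7% of cells, against 17.9% and 66.1% if the UMIs had been spread evenly, so the UMIs were concentrated in fewer cells. At 3 or more genes the even spread gives 1.64% in ASO-L1, near the observed share. At 5 or more it gives 0.0034% in ASO-L1, against 0.479% (0.344% to 0.649%) observed. In SO-L1 it gives 5.02e-06%, against 0.085% (0.028% to 0.198%) observed on 5 cells.

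**Figure D3:**
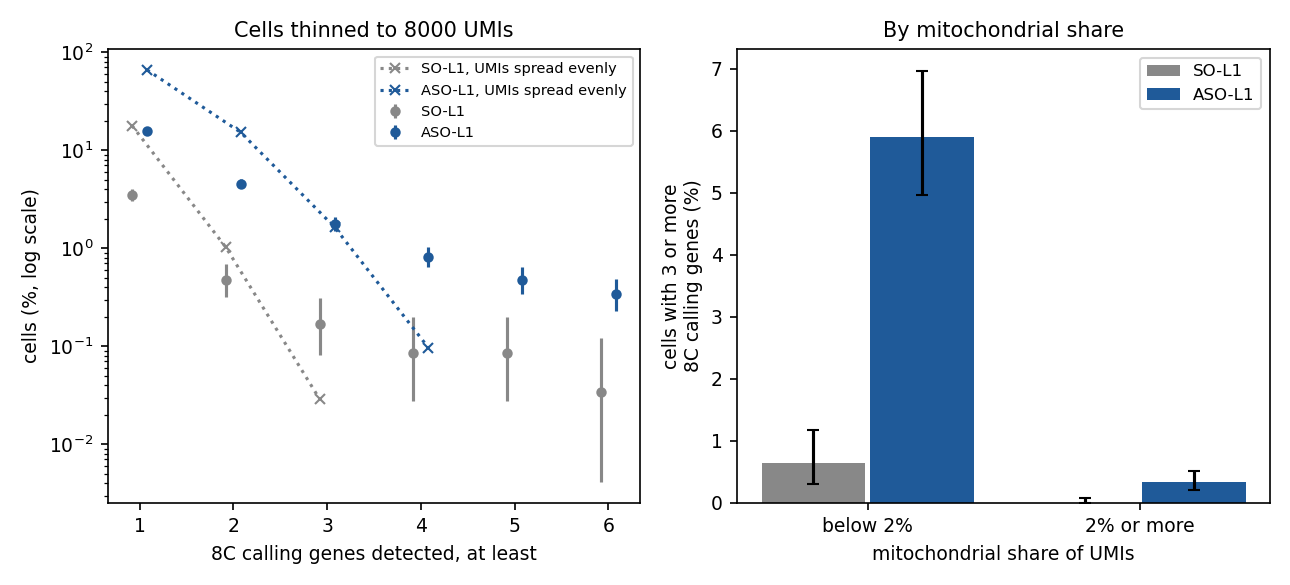
Left, the percent of thinned cells with at least a given number of 8C calling genes on a log axis, with 95% intervals as bars and crosses, drawn for the lower numbers of genes, for UMIs spread evenly. Right, the percent with 3 or more by mitochondrial share, at 5.91% in ASO-L1 cells below 2% and 0.644% in SO-L1 cells below 2%.

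Within each library, the cells with 3 or more calling genes differed from the rest beyond the genes that defined them. In ASO-L1, GNRH1, a hormone gene, was 102-fold higher in them (94.9 to 110), SLC34A2 98.0-fold, KLF17 78.4-fold, TRIM60 49.4-fold, VMO1 46.7-fold and DPPA3, a maternal factor, 27.1-fold. The Nodal inhibitor genes LEFTY2 and LEFTY1 stood at 0.125 and 0.132 times, POU5F1 at 0.518, SOX2 at 0.546, NANOG at 0.610, EZH2 at 0.284 and DNMT3B at 0.165 times. CDKN1A was 3.27-fold and GATA3 11.8-fold higher. In the 10 such SO-L1 cells, YPEL2 was 115-fold higher (98.0 to 133) on 190 UMIs, an interval that leaves out the spread between these cells. The heat shock gene HSPA1A was 51.3-fold, DPPA3 52.1-fold and KLF17 85.5-fold higher in them. LEFTY2 stood at 0.029, POU5F1 at 0.560, SOX2 at 0.351 and DNMT3B at 0.215 times. Of the cells with 3 or more calling genes, 100% in SO-L1 and 86.3% in ASO-L1 were below 2% mitochondrial UMIs. Among the rest the shares were 26.2% and 25.0%. No comparison with other low-mitochondrial cells was made. Differences such as that of CDKN1A, also higher in low-mitochondrial cells as a whole, are therefore not shown to belong to the cells with 8C genes.

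The lists of these cells against the rest gave medians of 7.16 in SO-L1 and 4.49 in ASO-L1 for the 8C genes outside the calling genes, and of −1.31 (−2.22 to −0.47) and −1.23 (−2.28 to −0.87) for general pluripotency genes. Targets of p53 had medians of 1.96 (1.19 to 2.21) and 0.63 (0.21 to 1.29), integrated stress response genes 1.73 and 0.68, and nucleolar genes 0.35 and 0.32. Mitochondrial genes had medians of −4.67 and −2.55 in these cells. Low-mitochondrial cells as a whole, against the other cells, had medians of 1.77 and 1.03 for p53 targets, 1.02 and 0.60 for integrated stress and −0.49 and −0.93 for general pluripotency, so these shifts are not shown to belong to the cells with 8C genes. Nucleolar genes had medians of −0.42 and −0.15 in low-mitochondrial cells, the opposite sign, with mitochondrial genes left out of that total. Naive genes had medians of 1.45 and 1.22 in the cells with 3 or more calling genes. Their members went both ways, such as DPPA3 above and DPPA4 at 0.417 times in ASO-L1. For lists of scarce genes in the 10 SO-L1 cells, the floor of 3 UMIs lifts members with no UMI, so those medians carry no direction. With 2 or more calling genes as the rule, the nucleolar median in SO-L1 was −0.13 and that of splicing factors −0.15, against 0.24 with 3 or more.

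Clustering gave 10 clusters. Cluster 8, of 325 cells, was 8C-like, with FAM151A, SLC34A2, DUXB and TPRX1 among its 10 leading genes by fold beside GNRH1 and VMO1, and it held 75.5% (68.1% to 81.9%) of the 163 cells with 3 or more calling genes. Of the cells in cluster 8, 37.8% had 3 or more calling genes, and the 8C genes could enter the clustering that formed it. With the 8C genes left out, 129 of the 163 cells lay in a cluster of 1350 cells, of which 9.56% had 3 or more. The other clusters had too few fixed markers among their leading genes to be named. IL24 and ECM1, which lead cluster 4, and CER1, which leads cluster 5, were among the genes highest in ASO-L1, and a cluster mostly of 1 library may be that library, so cluster sizes are not read as results. The cluster with the highest 8C median held 0.136% of SO-L1 and 3.70% of ASO-L1 cells, shares that depended strongly on the setting.

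Mitochondrial share divided the cells of both libraries, and the 8C genes differed with it. Below 2% lay 28.3% (27.2% to 29.4%) of SO-L1 and 27.9% (26.9% to 28.8%) of ASO-L1 cells, with 178 and 363 cells between 1% and 3%. All 10 SO-L1 cells and 132 of the 153 ASO-L1 cells with 3 or more calling genes were below 2%. Their median mitochondrial shares were 0.147% in SO-L1 and 0.182% in ASO-L1, against 8.14% and 6.57% in the rest. Low-mitochondrial cells thus held very little mitochondrial RNA, with medians of −5.66 and −5.32 (log2) for mitochondrial genes over the other cells. In SO-L1 none of 4350 cells at 2% or more had 3 or more calling genes, with an exact upper bound of 0.085%. Over the other cells of their library, low-mitochondrial cells had the keratin gene KRT17 at 64.2-fold in SO-L1 and 17.5-fold in ASO-L1, CDKN1A at 12.1-fold and 4.12-fold, ZSCAN4 at 37.1-fold and 17.4-fold, and NCL at 0.557 and 0.625 times. The 8C median of ASO-L1 over SO-L1 was 2.59 (1.65 to 3.03) in low-mitochondrial cells and 2.35 (0.64 to 3.23) in the others. In each class the libraries lay mostly in different clusters: among clusters with a median share below 2%, cluster 3 held 1332 SO-L1 and 607 ASO-L1 cells and cluster 4 held 101 and 1143, and above it cluster 1 held 3622 and 2025 and cluster 2 held 7 and 2899. Ratios within a class therefore do not compare matched cells. The medians of primed, p53 target, glycolysis and mitochondrially encoded genes, given above, had the opposite sign in low-mitochondrial cells. Other lists whose small median over all cells changed sign there were PRC2 factors (−0.10), repeat silencing (0.10), neuroectoderm (0.04), primitive endoderm (−0.06) and oocyte genes (0.23).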

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

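The tests of loss of cytoplasm, doublets, p53 targets, the share of low-mitochondrial cells, and swapped reads and depth behind the 8C genes were chosen only after the result was seen. The shared barcode sequences and the split by mitochondrial share were noticed in the data. In cells with 3 or more 8C calling genes against the rest, ID3 had a log2 ratio of 1.81 in SO-L1 and −1.20 in ASO-L1, opposite ways in the libraries. VIM had log2 ratios of 0.66 in SO-L1 and −0.93 in ASO-L1 in that comparison. Neither difference between libraries was tested, since SO-L1 had 10 such cells from 1 library. No group has enough libraries to look for one far from the others. Among barcodes with under 1000 genes, those of SO-L1 that hold more UMIs in ASO-L1 carried 8C calling genes at 117 CPM (107 to 128), against 15.2 CPM in kept SO-L1 cells and 115 CPM in kept ASO-L1 cells. The 350 ASO-L1 barcodes with under 1000 genes, under 20% mitochondrial UMIs and not deeper in SO-L1 carried them at 292 CPM (236 to 357).

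The libraries shared 6105 barcode sequences, and 5306 SO-L1 barcodes (40.6%) held a median of 1.34% of the UMIs of their ASO-L1 partner. Reads swapped between the libraries are a candidate explanation: the shallow barcode was closer to the cell of the same sequence than to a random cell in 99.6% of SO-L1 and 96.1% of ASO-L1 pairs. Free RNA of the own library carries no link to a barcode of the other library, and the 99.6% argues against it as the main source. The test set beforehand for free RNA was undecided: 28.9% (27.7% to 30.2%) of shallow SO-L1 barcodes lay closer to the SO-L1 pool, between the preset bounds of 25% and 50%, so some free RNA stays open. No biological explanation was tested.

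Most cells with 3 or more 8C genes had under 2% mitochondrial UMIs. Loss of cytoplasm would lower ribosomal protein genes, whose median in low-mitochondrial over other cells was −0.075 in SO-L1 and −0.03 in ASO-L1, although the nuclear RNAs MALAT1 (2.26-fold and 1.85-fold) and NEAT1 (7.40-fold and 3.45-fold), looked at afterwards, were higher. Doublets would hold more UMIs, whereas the median UMIs of these cells were 0.638 times those of the rest in SO-L1 and 0.750 times in ASO-L1. As a hypothesis, the low-mitochondrial state may go with activity of p53 targets, whose medians were 1.77 and 1.03. Integrated stress and interferon genes were higher too, so p53 is not singled out.

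The higher 8C genes in ASO-L1 do not come down to a different share of low-mitochondrial cells, which would leave no difference within them, since the 8C median there was 2.59. Swapped reads would have to bring 8C genes into ASO-L1, but its shallow barcodes deeper in SO-L1 carried them at 22.9 CPM (12.2 to 39.2), below the 115 CPM of its kept cells. A deeper ASO-L1 library would leave no difference at equal depth, where the shares of cells with 3 or more calling genes had a ratio of 10.5 with intervals apart. The medians set beforehand for these 2 (2.03 without the barcodes deeper in the other library, 2.22 in thinned cells) decide nothing, since few kept cells were removed and a ratio of summed CPM does not shift with depth. An effect of the oligonucleotide stays open as a hypothesis, together with a different mix of cells within the mitochondrial classes and any other difference between the 2 cultures or library preparations, which 1 library per group cannot separate from it.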

How the results depend on the processing

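No paired analysis was possible because each group has 1 library. The alternatives by mitochondrial class, shared barcodes, highest Scrublet scores, 4 or more genes and clusters without 8C genes were chosen after the data were seen. Leaving out called doublets removed no cell and gives no value. The 8C list median kept its direction under all 13 alternatives (1.91 to 2.76). Some of these could hardly have reversed it: scalings that shift all genes alike, thinned sums and leaving out barcodes deeper in the other library. Other lists stayed within their interval in 312 alternatives and left it in 12. Named genes stayed within theirs in 817 alternatives and left it in 643. Reversals were looked for only in genes at least 1.5-fold apart whose interval excludes 1, and none was found there. The causes of the shifts below were not tested, except where fewer cells, genes or UMIs enter by construction. No scaling moved the median of all genes by over 0.1, the largest shift being 0.05 under median-of-ratios scaling.

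In cells below 2% mitochondrial UMIs alone the medians were −0.60 for general pluripotency, −0.54 primed, 0.43 nucleolus, −0.13 p53 targets, 0.39 S phase, 0.59 G2M, 0.17 glycolysis, 0.16 ZNF genes and 0.091 mitochondrial genes. In the other cells general pluripotency was −0.0069 and p53 targets 0.59, or 0.57 and inside its interval with mitochondrial genes left out of the total. Median-of-ratios scaling put ZNF genes at 0.16. Genes at least 2-fold higher numbered 1110 in cells from 2% and 1071 in thinned cells, and 3792 at 1.5-fold. Genes lower numbered 2573 in cells below 2%, 834 in thinned cells, 3919 at 1.5-fold and 2035 from 10 UMIs.

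The SO-L1 share of cells with 3 or more 8C genes was 0.644% below 2% mitochondrial UMIs, 0% from 2%, 0.474% with 2 or more genes and 0.336% without thinning. The ASO-L1 share was 5.91% below 2%, 0.332% from 2%, 4.58% with 2 or more genes, 0.817% with 4, 0.479% with 5, 4.90% without thinning, 1.23% and 2.92% at the lower and higher thinning depths, and 1.25% without multigene families.

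In SO-L1 cells with 8C genes against the rest, 2 or more genes gave medians of 1.01 for amnion, −0.13 nucleolus, −0.15 splicing (these with the opposite sign), 0.26 ZNF genes and 0.11 ribosomal proteins. With 5 or more, which left 5 SO-L1 cells, they were 3.64 amnion, 4.33 primitive endoderm, 4.71 PRC2 target regulators, 1.42 ZNF genes and −0.21 ribosomal proteins. Thinned sums gave 3.45 amnion, 1.41 ZNF genes and −0.16 ribosomal proteins. In so few cells the floor of 3 UMIs lifts members with no UMI, so these SO-L1 medians of scarce genes carry no direction. In ASO-L1, 5 or more genes gave 1.69 amnion, 1.38 primitive endoderm, 0.14 ZNF genes and −2.38 mitochondrial genes. Thinned sums gave −0.82 PRC2 target regulators (1.53 on all UMIs), −0.22 interferon, 0.18 ribosomal proteins and −2.72 mitochondrial genes. Mitochondrial genes were at −2.10 with 2 or more genes and −3.04 without the highest Scrublet scores.

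Resolution 1.0 gave 18 clusters. The cluster with the highest 8C median held 3.76% of SO-L1 and 22.9% of ASO-L1 cells at resolution 0.3, 1.78% and 14.5% without the 8C genes, and 5.45% of ASO-L1 cells on all UMIs. These planned shares moved in 5 of 8 alternatives. The measure added after that, the share of cells with 3 or more 8C genes in 1 cluster, was 98.2% at resolution 0.3. That cluster was larger, with 2181 cells, of which 7.34% had 3 or more. Median UMIs in SO-L1 were 5773.5 without a filter, 43201.5 with the stricter one and 41843 without the highest Scrublet scores. They were 43105 without the 264 kept barcodes deeper in ASO-L1. In ASO-L1 they were 47130, 54964 and 53094 under the first 3 of these. LEUTX and DUX4 are near the floor at this depth.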

Other observations

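The test of gene length was set before its result was seen. Cells below 2% mitochondrial UMIs differed from the other cells of their library in many genes besides the 8C list. Targets of p53 were at least 1.5-fold higher in 24 of 27 in SO-L1 and 19 of 27 in ASO-L1. Interferon response genes were higher in 18 of 26 in each (medians 1.09 and 1.03), with IFIT2 at 78.5-fold in SO-L1. Genes named by the rule included ANXA1 at 36.6-fold, S100A6 at 21.4-fold and EMP1 at 74.9-fold in SO-L1, and KRT17 and KRT16 at 17.5-fold and 15.8-fold in ASO-L1. Trophectoderm genes had medians of 0.72 and 1.25. General pluripotency genes were lower, with medians of −0.49 and −0.93, as were S phase genes at −0.48 and −0.31. G2M genes were lower in SO-L1 (median −0.43, 15 of 54 lower and 0 higher) but not in ASO-L1 (−0.05, 1 lower and 9 higher), and nucleolar genes had medians of −0.42 and −0.15. These differences between the libraries were not tested.

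Within low-mitochondrial cells, the ASO-L1 library had G2M genes at a median of 0.59 (27 of 54 higher, 1 lower), nucleolar genes at 0.43 (17 of 55 higher, 1 lower) and interferon genes at −0.76 (14 of 26 lower, 6 higher). EZH2 stood at 0.433 times and SOX2 at 0.447 times the SO-L1 level there, and SNAI1, a transcription factor of epithelial to mesenchymal transition, was 19.0-fold higher. In the other cells, cholesterol genes had a median of −0.58 (10 of 22 lower, 0 higher), p53 targets 0.57 (13 of 27 higher, 0 lower) and integrated stress genes 0.78, with CCR7, a chemokine receptor, at 55.3-fold. None of these ratios compares matched cells, since the libraries lay mostly in different clusters within a class (cluster 4, low in mitochondrial UMIs, held 101 SO-L1 and 1143 ASO-L1 cells).

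Longer genes were lower in ASO-L1. The difference between the longest 20% and the shortest 20% of genes was −0.39 (log2, median difference) over all cells, −0.69 in low-mitochondrial cells and −0.31 in the others, with lengths known for 97.1% of 22863 genes. The test set for this only restates the difference by class, with −0.31 as the smaller value, and so supports no explanation. Whether intronic counting, LINE1 content of introns or library preparation lies behind it was not tested.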
